A study of Homo sapiens with 16 samples.

How the data were processed

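Polyadenylated RNA was sequenced from HCT116 cells, a human colorectal cancer line, that carried either wild-type CDK8 or the CDK8as/as genotype, in which both copies of the gene encode an analog-sensitive kinase that a bulky ATP analog can inhibit. Cells were given 3MB-PP1, which is such an analog, or its vehicle (DMSO), and were kept in ambient oxygen (normoxia) or in 1% oxygen (hypoxia) for 24 h, per the labels. The 8 combinations of genotype, compound and oxygen were each represented by 2 libraries, which the labels call independent biological replicates. The dose of 3MB-PP1 and the time at which it was added are not given in the labels. Per the labels' protocols, cells were plated the day before treatment, total RNA was extracted with a phenol reagent, polyadenylated RNA was selected on oligo-dT beads, and libraries were made with an Ion Torrent total RNA kit and sequenced on an Ion Torrent Proton.

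The deposited table holds counts per gene symbol, made by the authors as whole numbers of reads for 25369 symbols and 16 libraries. Per the design text, the authors aligned reads with GSNAP to hg19, counted them per gene with HTSeq-count and tested genes with DESeq2, whose results were not used here. The submitters' processing notes also name FastQC 0.11.2, SAMtools 0.1.19, Picard 1.129, HTSeq 0.6.1 and deepTools 2.2.2. The strand setting of the counting and the version of the gene annotation are not given in the sources used here. The columns were whole numbers with a different total in each library, no library was pooled, and no column was left without a group (0 unmapped columns). The mitochondrially encoded genes are absent from the table.

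Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures were made with Python 3.11.15. Of the 22909 symbols with any count, 15562 passed filterByExpr with its default settings and were tested. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted over all 16 libraries (glmQLFit and glmQLFTest, robust). Each comparison was a contrast of group means, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Errors on log2 fold changes are standard errors of the fit, with n = 2 libraries per group, and levels are TMM-scaled CPM with the standard deviation of the 2 libraries. The common biological coefficient of variation was 0.152. Total counts ran from 12043145 to 38805502 per library with a median of 28578824, so that 1 count was worth 0.0258 to 0.0830 CPM and the floor of 3 counts was 0.0773 to 0.249 CPM. The floors cover counting error only, while the standard errors and standard deviations also hold differences between replicates.

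The 12 comparisons of a pair of groups were hypoxia against normoxia, compound against vehicle and CDK8as against WT, each at every setting of the other factors. Differences between effects were tested as interaction contrasts of the same model: genotype by compound in each oxygen level, compound by oxygen in CDK8as cells, and genotype by oxygen with vehicle. The main test, the comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The genotype by oxygen contrast, the offsets for GC content and expression level, the circadian clock and single-exon gene lists and the tests of technical explanations were chosen after results had been seen.

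The 31 fixed gene lists, each for a pathway, complex, cell type or RNA class, were glycolysis, other HIF targets, the HIF pathway, the Mediator kinase module and core, cholesterol and fatty acid synthesis, interferon response, Wnt targets, immediate early genes, p53 targets, E2F targets, G2/M genes, MYC targets in ribosome biogenesis, cytosolic ribosomal proteins, nuclear oxidative phosphorylation genes, the TCA cycle, mitochondrially encoded genes, ATF4 targets, the unfolded protein response of the endoplasmic reticulum (ER), heat shock, NF-kB targets, TGF-beta/SMAD targets, intestinal epithelium, mesenchymal genes, metallothioneins, replication-dependent histones, RNAs without a poly(A) tail, and leukocyte, fibroblast and endothelial markers. Lists with at least 5 tested members were tested with limma's camera (competitive, two-sided, preset inter-gene correlation 0.01) with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated from the residuals, and fry, which asks whether the members of a list move 1 way on balance, were run beside it. Members were also adjusted over the list alone. Lists of the 200 genes with the smallest p and a change of at least 2-fold in hypoxia were derived in vehicle-treated cells of 1 genotype and tested in comparisons that share no library with them. Overlaps of calls were set against the product of the shares of the genes called, for comparisons that share no library.

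The text names CDK8, CDK19, CCNC, MED12 and MED13, then from each comparison of 2 groups up to 8 genes with the highest and 8 with the lowest log2 fold change among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries, up to 6 of each in the interactions, and up to 4 members per list with the smallest adjusted p. XIST and Y-linked genes were passed over. SLC16A1, ZNF395, MED15 and MED22, list members that went against their list or among several in a split list, and the clock genes other than CRY1 were named after their values were seen, except where the rule also named them. Coordinates are GRCh37, from GENCODE v44 lifted to that build, which is not the annotation the authors used, and 23031 of the 25369 symbols matched it. Of 192 genes considered for the text, 190 were located, and 54 share exonic bases with another gene. Reads there could have been assigned to either gene or left uncounted, and the values are uncertain to that degree. The metallothioneins are near-identical paralogs, and counts of single members are uncertain for the same reason.

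Alternatives changed 1 choice at a time: RLE in place of TMM, no filter on low counts, a term for the replicate number (replicate block), DESeq2 in place of edgeR, a fit on only the groups compared, and each library left out in turn, in which case the remaining library of its group was assumed to vary like the other groups. Added after the data were seen were an edgeR offset from a loess trend of each library against GC content, available for 96.0% of tested genes, and an offset against mean expression. RLE and the offset settings were applied to every comparison and fixed list, but not to the lists derived from the hypoxia comparisons.

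The pipeline was tested on simulated counts with the depths of these libraries. Each gene was given the same spread in every group, so the larger replicate differences of WT DMSO normoxia were not reproduced. Of 15562 genes, 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold. The changed genes were drawn from those above a low expression cutoff, and no other gene differed between groups. Far fewer genes thus changed than were called with hypoxia (6034 in vehicle-treated WT cells). Recovery at such a share of changed genes was not tested. In the contrast of hypoxia with normoxia in vehicle-treated WT cells 11.9%, 70.2% and 100% of the changed genes were called, in compound against vehicle in hypoxic CDK8as cells 13.4%, 68.7% and 98.5%, and in the genotype by compound contrast in hypoxia 2.98%, 16.4% and 93.9%. Unchanged genes made up 7 of 128, 7 of 127 and 9 of 84 calls in these contrasts. Of 200 random gene lists, 3% had a camera p under 0.05. The simulated genes varied independently, so this does not test lists of correlated genes. Groups of 2 are too small for an informative permutation of samples or an outlier test within a group, and neither was run.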

Results

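RNA was measured in 16 libraries of HCT116 cells, 2 for each of 8 groups that combine genotype (WT or CDK8as, short for CDK8as/as), compound (DMSO or 3MB-PP1, written 3MB) and oxygen (normoxia or hypoxia). CDK8 is a kinase of the Mediator complex, which links transcription factors to RNA polymerase II, and CDK19 is its paralog. Hypoxia lasted 24 h at 1% oxygen. Total counts ran from 12043145 in WT 3MB normoxia replicate 2 to 38805502 in WT DMSO normoxia replicate 1. The first principal component held 43.5% of the variance and separated the oxygen levels, and the second held 22.7% and separated the genotypes. The replicates of WT DMSO normoxia differed more than those of any other group, with a chi-square per degree of freedom of 145 against 10.5 to 30.1. In hypoxia the 10 most abundant genes took 6.65% to 8.38% of a library's counts, against 3.62% to 4.30% in normoxia.

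**Figure D1:**
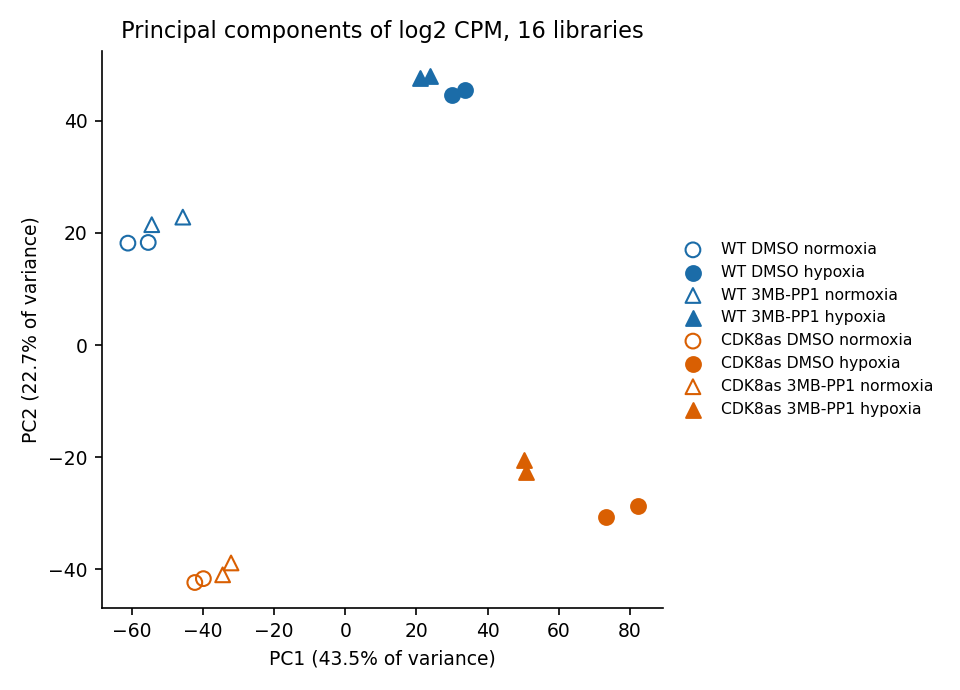
Principal components of log2 CPM, 1 point per library, with the share of variance of each component (43.5% and 22.7%) on the axes. The libraries of each oxygen level lie on 1 side of the first component and those of each genotype on 1 side of the second.

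CDK8 itself (13:26828241-26995119) was present at 27.4 ± 4.9 CPM (SD, n = 2) in WT DMSO normoxia and at 28.4 ± 0.4 CPM in CDK8as DMSO normoxia, and it was called in none of the comparisons of group pairs by edgeR. Its log2 change from WT to CDK8as was 0.05 ± 0.16 (SE, adjusted p = 0.89) in normoxia with vehicle. CDK19 (6:110931181-111137161) rose in hypoxia in all 4 backgrounds, from 21.5 ± 0.8 to 45.8 ± 4.4 CPM in WT cells with vehicle (log2 1.09 ± 0.16, adjusted p = 6.2e-05) and by 1.05 ± 0.16, 1.00 ± 0.16 and 0.90 ± 0.15 in the others. MED12 and MED13, which hold the kinase in the complex, rose in hypoxia in WT cells with vehicle by 0.88 ± 0.23 (adjusted p = 0.0057) and 0.51 ± 0.17 (adjusted p = 0.024). The call of MED13 was lost with the expression offset (adjusted p = 0.0843) and without WT DMSO normoxia replicate 1 or either WT DMSO hypoxia library. A fit on only the groups compared called neither MED12 (0.111) nor MED13 (0.128). CCNC, the cyclin partner of CDK8, was called in no comparison of group pairs; its exons overlap those of TSTD3.

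**Figure D2:**
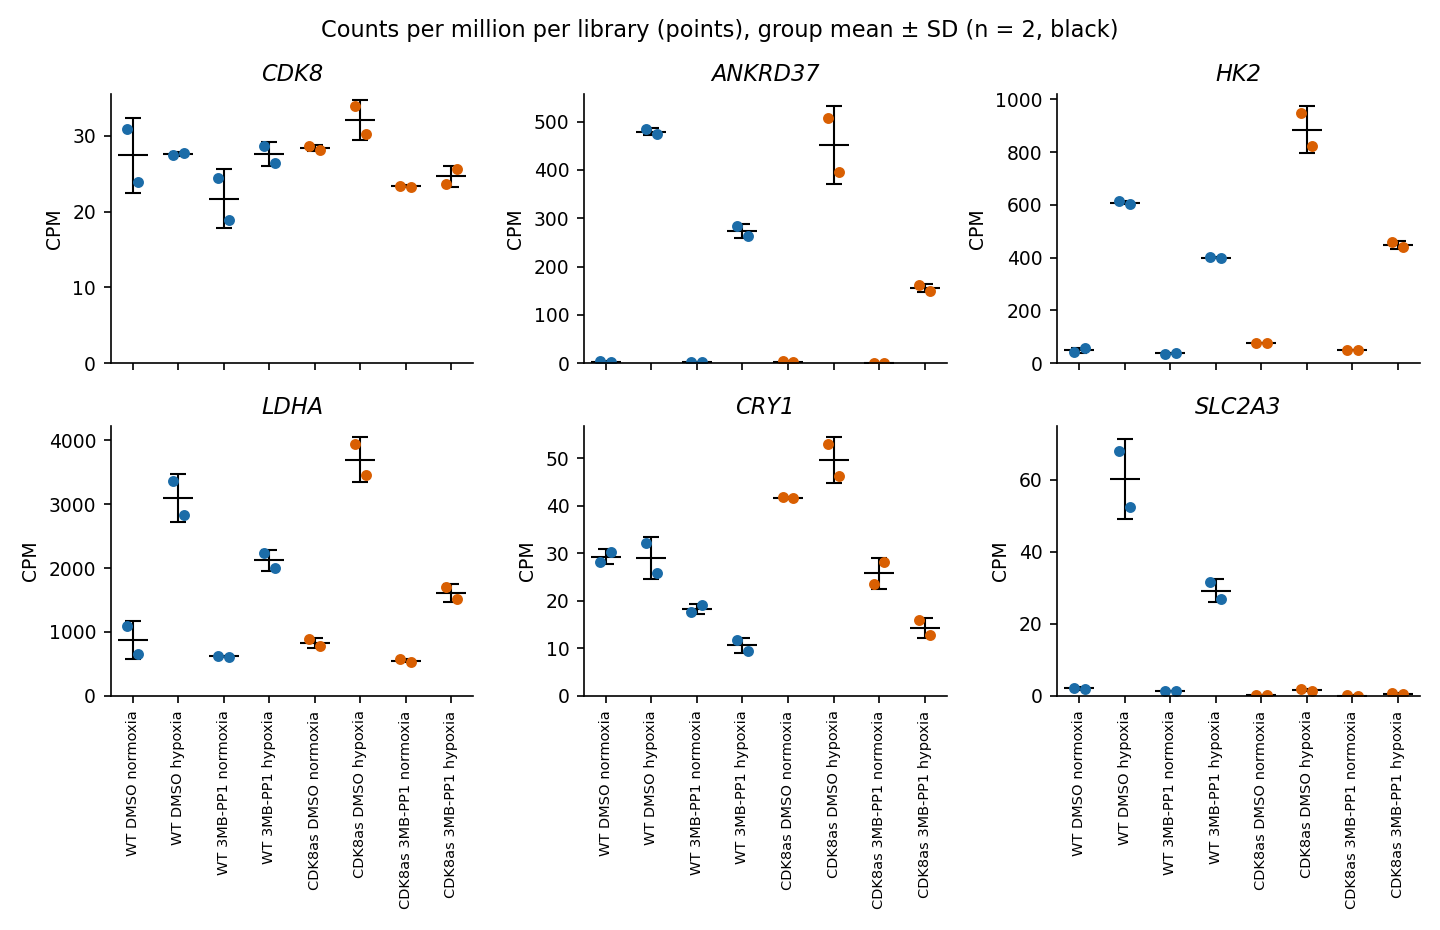
CPM on a linear axis in each of the 8 groups for CDK8, ANKRD37, HK2, LDHA, CRY1 and SLC2A3, with points for libraries and bars for the mean and SD. ANKRD37 went from 2.83 to 479 CPM with hypoxia in WT DMSO cells, and HK2 was at 885 CPM in CDK8as DMSO hypoxia against 449 CPM with 3MB.

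The comparison of hypoxia with normoxia in vehicle-treated WT cells asked which genes respond to low oxygen with CDK8 intact. Genes for glucose use and for known targets of the HIF transcription factors rose. ANKRD37 (4:186317175-186321782), an ankyrin repeat gene, rose by log2 7.36 ± 0.34 (SE, n = 2 per group, adjusted p = 1.7e-09), ANGPTL4, a secreted regulator of lipid uptake, by 7.09 ± 0.32, and CA9 (9:35673925-35681156), a cell-surface carbonic anhydrase, by 5.24 ± 0.44. HK2, the first enzyme of glycolysis, rose by 3.63 ± 0.16, PFKFB4 by 3.68 ± 0.14 and PDK1, which closes the mitochondrial route of pyruvate, by 3.24 ± 0.15. NDRG1, IGFBP3, DDIT4 and BHLHE40 rose by 5.13 ± 0.21, 4.91 ± 0.36, 4.73 ± 0.17 and 4.04 ± 0.17. FAM111B, a protease gene tied to DNA replication, fell by 3.10 ± 0.36. C14orf169, a ribosomal oxygenase, PYCRL, an enzyme of proline synthesis, and DDX28, a helicase of mitochondrial ribosomes, changed by -3.06 ± 0.27, -2.71 ± 0.18 and -2.54 ± 0.27. The exons of ANKRD37, CA9 and PYCRL overlap those of UFSP2, ARHGEF39 and TIGD5, so these values are uncertain to that degree.

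By list, 22 of 24 glycolysis genes rose (median log2 1.63, camera adjusted p = 3.2e-43, and adjusted p = 8.3e-05 with an estimated correlation), and 22 rose adjusted over the list alone. SLC16A1, a lactate exporter on that list, fell by 0.81 ± 0.13 (adjusted p = 2.0e-04). All 44 tested other HIF targets rose, over all genes and adjusted over the list alone (median 2.59, adjusted p = 3.8e-106). Of 14 HIF pathway genes, EPAS1 and ARNT rose by 1.52 ± 0.18 and 0.79 ± 0.13 while HIF1A and CUL2 fell by 0.75 ± 0.15 and 0.71 ± 0.14, calls lost in a fit on only the groups compared (adjusted p = 0.0530 and 0.0679). That list was not called (adjusted p = 0.94, median -0.13 but mean 0.06). Immediate early genes rose in 29 of 38 cases with 2 lower (median 1.27, adjusted p = 1.0e-17), and 30 rose adjusted over the list alone. FOSL2 and DUSP1 were among them at 2.80 ± 0.14 and 3.41 ± 0.20. Genes of cholesterol synthesis rose in 17 of 25 cases with 1 lower, 18 adjusted over the list alone (median 0.73, adjusted p = 1.2e-05), with INSIG1 at 2.63 ± 0.22. E2F targets, which copy DNA, fell in 37 of 40 cases (median -1.22, adjusted p = 9.0e-21). MYC targets of ribosome biogenesis fell in 25 of 31 cases (median -0.85, adjusted p = 2.6e-11), and heat shock genes in 11 of 15 (median -0.87, adjusted p = 4.7e-05). Adjusted over the list alone, as many fell. MCM10, NOP56 and HSPA8 fell by 1.94 ± 0.14, 1.31 ± 0.15 and 1.66 ± 0.20. Of these lists, the glycolysis and other HIF target calls held with an estimated correlation. The calls of immediate early, MYC, E2F, heat shock and cholesterol genes did not (adjusted p = 0.062, 0.062, 0.080, 0.33 and 0.33 with an estimated correlation).

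Among the remaining lists of this comparison, 9 of 16 TGF-beta/SMAD targets rose and 3 fell (median 0.62, adjusted p = 0.013, and adjusted p = 0.080 with an estimated correlation). ID3 fell by 1.47 ± 0.18. Mesenchymal genes rose in 8 of 10 cases (median 0.89, adjusted p = 0.015, and adjusted p = 0.33 with an estimated correlation). Genes of the ER unfolded protein response rose in 9 of 19 cases with 2 lower, 11 and 3 adjusted over the list alone (median 0.45, adjusted p = 0.016, and adjusted p = 0.66 with an estimated correlation). That call was lost with the expression offset (0.134), without WT DMSO normoxia replicate 2 (0.153) and without WT DMSO hypoxia replicate 1 (0.097). Intestinal epithelium genes rose in 6 of 12 cases with 1 lower (median 0.49, adjusted p = 0.036, and adjusted p = 0.53 with an estimated correlation), with ELF3 up by 2.56 ± 0.18. Fatty acid synthesis genes rose in 6 of 13 with 1 lower (median 0.35, adjusted p = 0.040, and adjusted p = 0.71 with an estimated correlation). The intestinal call was lost without WT DMSO normoxia replicate 2 (0.0623) or WT DMSO hypoxia replicate 2 (0.0721), and the fatty acid call without WT DMSO normoxia replicate 1 (0.218) or WT DMSO hypoxia replicate 2 (0.0692). These lists were not called: p53 targets (12 higher and 5 lower of 30, adjusted p = 0.075), metallothioneins (4 higher of 9, 0.075), cytosolic ribosomal proteins (3 higher of 50, 0.086) and oxidative phosphorylation (1 higher and 6 lower of 50, 0.18). Over omitted libraries these 4 were called at the lowest adjusted p, 0.020, 0.029, 4.0e-09 and 3.1e-05. The ribosomal protein list was called higher without WT DMSO normoxia replicate 1 or WT DMSO hypoxia replicate 2 (median -0.16 to 0.78 over omissions). The oxidative phosphorylation list was called without WT DMSO normoxia replicate 2 or WT DMSO hypoxia replicate 1 (median -0.48 to 0.19, 1 to 29 lower). Nor was the Mediator kinase module (4 higher of 7, 0.16) or core (3 higher and 5 lower of 26, 0.37), where MED15 and MED22 changed by 1.38 ± 0.27 and -1.42 ± 0.19, the first not called in a fit on only the groups compared. Neither NF-kB targets (7 higher and 3 lower of 18, 0.37), histones (3 higher of 13, 0.37) nor interferon response genes (5 higher and 8 lower of 34, 0.39) were called. The same held for the TCA cycle (3 higher and 7 lower of 18, 0.47), ATF4 targets (3 higher and 6 lower of 25, 0.71), Wnt targets (2 higher and 4 lower of 17, 0.81, median 0.02 but mean -0.17) and G2/M genes (2 higher and 3 lower of 30, 0.86). RNAs without a poly(A) tail had 1 higher of 8 (0.86), leukocyte markers 1 higher of 6 (0.86, median -0.12 but mean 0.34), and endothelial markers 0 of 5 (0.93). Fibroblast markers had 1 higher of 4, too few to test, and none of the 13 mitochondrially encoded genes is in the table. The median of ribosomal protein genes was 0.27, and -0.11 with the expression offset.

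At an adjusted p under 0.05, edgeR called 6034 of 15562 genes in this comparison, 2939 higher and 3095 lower, of which 1311 and 1074 changed at least 2-fold. The count was 3997 without WT DMSO hypoxia replicate 2, and 2428 in a fit on only the 4 libraries compared. WT DMSO normoxia replicate 1 stood apart from its replicate, and of the ANKRD37, HK2 and CA9 calls none was lost without either.

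The same comparison in vehicle-treated CDK8as cells asked whether the hypoxic response occurs with the engineered kinase. ANKRD37 rose by log2 6.93 ± 0.34 (SE, n = 2 per group, adjusted p = 1.5e-09), NDRG1, a stress response gene, by 5.99 ± 0.22, ADM, a vasodilating peptide, by 5.59 ± 0.21 and MXD1, a MYC antagonist, by 5.08 ± 0.25. ENO2, a glycolytic enolase, rose by 4.25 ± 0.18, and MSMO1, an enzyme of cholesterol synthesis, by 3.45 ± 0.20. GPR15, a chemoattractant receptor, AXIN2, a Wnt target, and BMP4, a secreted growth factor, changed by -4.27 ± 0.53, -2.42 ± 0.30 and -1.96 ± 0.14. Of 24 glycolysis genes 22 rose and SLC16A1 fell (median 1.83, adjusted p = 1.7e-29, and adjusted p = 3.4e-04 with an estimated correlation). Of 44 other HIF targets 40 rose, 41 adjusted over the list alone (median 2.82, adjusted p = 4.7e-73). Cholesterol synthesis genes rose in 21 of 25 cases with 2 lower (median 1.43, adjusted p = 2.0e-14, and adjusted p = 0.11 with an estimated correlation). Metallothioneins, which bind zinc and other metals and are near-identical paralogs, rose in 7 of 9 cases (median 1.70, adjusted p = 7.0e-05, and adjusted p = 0.14 with an estimated correlation), with MT2A at 2.49 ± 0.21. E2F targets fell in 34 of 40 cases with 1 higher (median -1.22, adjusted p = 6.3e-14, and adjusted p = 0.22 with an estimated correlation). Cytosolic ribosomal protein genes rose in 38 of 50 cases, 41 adjusted over the list alone (median 0.82, adjusted p = 2.3e-05, and adjusted p = 0.72 with an estimated correlation). With the expression offset their median was 0.15 and 0 were called (adjusted p = 0.612). In all, 7383 genes were called, 3700 higher and 3683 lower, and no single library moved that count by more than 1.5 times (5660 to 6272).

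Calls of the pair of genotypes overlapped. With vehicle 2331 genes rose in both, against 699 from the product of the shares called, 2383 fell in both against 732, and 14 went opposite ways against 1431. The Spearman correlation of log2 changes across genes, which are not independent replicates, was 0.747. Of the 200 genes that rose most firmly in WT cells, 199 were called higher in CDK8as cells, and all 200 of those that fell were called lower. The interaction of genotype with oxygen asked whether the response differs in size. FAM83A, a signalling adaptor, rose more in CDK8as cells by log2 3.66 ± 0.59 (SE, n = 2 per group, adjusted p = 0.0078), SOCS1, a cytokine signalling inhibitor, by 3.14 ± 0.42, and CSTB, a protease inhibitor, by 2.50 ± 0.25. FAT4, a cadherin, and PDK4, a pyruvate dehydrogenase kinase, differed by -2.64 ± 0.36 and -2.55 ± 0.41, and the PDK4 call was lost in a fit on only the groups compared. Cholesterol synthesis genes differed upward in 5 of 25 cases, 16 adjusted over the list alone (median 0.80, adjusted p = 3.6e-15, and adjusted p = 0.14 with an estimated correlation), among them IDI1, an isomerase of that pathway, at 1.26 ± 0.22. Metallothioneins differed upward in 3 of 9 cases, 4 adjusted over the list alone (median 0.92, adjusted p = 4.3e-07, and adjusted p = 0.14 with an estimated correlation), with MT2A at 1.67 ± 0.28. The IDI1 call was lost in a fit on only the groups compared (0.169) and in 4 of the 8 omissions of a library, the MT2A call in 3. For both these were the omissions of WT DMSO hypoxia replicate 2, CDK8as DMSO normoxia replicate 2 and CDK8as DMSO hypoxia replicate 1, and for IDI1 also CDK8as DMSO normoxia replicate 1 (0.0550 to 0.0704 for IDI1 and 0.0506 to 0.0615 for MT2A). G2/M genes had a median of 0.42 (adjusted p = 2.9e-07, and adjusted p = 0.48 with an estimated correlation), and 0.12 to 0.66 over omitted libraries. Ribosomal protein and oxidative phosphorylation genes had medians of 0.56 (adjusted p = 2.9e-07) and 0.38 (adjusted p = 1.8e-06). Neither call held with an estimated correlation (adjusted p = 0.76 for both). The glycolysis list did not differ (median 0.09, mean -0.01, adjusted p = 0.93, median -0.19 with the expression offset), nor did the other HIF targets (adjusted p = 1). The interaction called 199 genes, 91 higher and 108 lower, against 12 (10 higher and 2 lower) in a fit on only the groups compared and 574 (214 higher and 360 lower) in DESeq2. That count was 2982 without WT DMSO normoxia replicate 2. It was 84 and 46 without WT DMSO hypoxia replicates 1 and 2, 57 and 47 without CDK8as DMSO normoxia replicates 1 and 2, and 39 without CDK8as DMSO hypoxia replicate 1.

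Hypoxia with 3MB asked the same of cells given the compound. In WT cells ANKRD37 rose by log2 7.19 ± 0.35 (SE, n = 2 per group, adjusted p = 4.0e-09), ANGPTL4 by 6.43 ± 0.31, CA9 by 5.96 ± 0.50 and NDRG1 by 4.26 ± 0.21. In CDK8as cells CA9 rose by 6.93 ± 0.56, ADM by 5.29 ± 0.21 and NDRG1 by 4.74 ± 0.21. PYCRL and GPR15 changed by -3.01 ± 0.19 and -3.20 ± 0.47. Glycolysis genes rose in 22 of 24 cases with 1 lower in each genotype (medians 1.64 and 1.43, adjusted p = 2.8e-55 and 9.6e-39), and other HIF targets in 42 and 41 of 44 (medians 2.29 and 2.34), all 4 calls holding with an estimated correlation. E2F targets fell in 36 and 30 of 40 cases (medians -1.08 and -0.81, adjusted p = 0.11 and 0.27 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 25 cases with 1 lower in WT cells (median 0.60, adjusted p = 0.24 with an estimated correlation) and in 22 in CDK8as cells (median 1.14, adjusted p = 0.039 with an estimated correlation). Called genes numbered 4488 in WT cells, 2076 higher and 2412 lower, and 4866 in CDK8as cells, 2367 higher and 2499 lower. In WT cells the count was 2636, 2935 and 2603 without 3MB normoxia replicate 2 and 3MB hypoxia replicates 1 and 2. In CDK8as cells it was 2996, 3183 and 3220 without 3MB normoxia replicate 1 and 3MB hypoxia replicates 1 and 2. Of these, 1610 rose in both genotypes against 316 from the shares called, and 5 were opposite against 700. The Spearman correlation across genes was again 0.747.

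The comparison of 3MB with vehicle in hypoxic CDK8as cells asked which genes change with the compound in low oxygen where the kinase is analog-sensitive. Alone it does not separate inhibition of that kinase from other actions of 3MB, which the genotype by compound contrast below tests. HK2 (2:75061254-75120486) fell from 885 ± 89 to 449 ± 15 CPM (SD, n = 2), a log2 change of -0.98 ± 0.14 (SE, adjusted p = 0.0015). LDHA (11:18416107-18429972), which makes lactate, fell by 1.20 ± 0.19 (adjusted p = 0.0028). NDRG1 and ANKRD37, both raised by hypoxia, fell by 1.25 ± 0.18 and 1.53 ± 0.26. CRY1 (12:107385142-107487327), a repressor of the circadian clock, fell by 1.79 ± 0.17 (adjusted p = 3.0e-04). PDGFA, a growth factor, SULT2B1, a sterol sulfotransferase, and DUSP1, a phosphatase of MAP kinases, changed by -1.69 ± 0.18, -1.64 ± 0.21 and -1.62 ± 0.18. SPOCD1, a gene of germline DNA methylation, rose by 1.89 ± 0.25, PKD2, a calcium channel, by 1.76 ± 0.19, DEPTOR, an inhibitor of mTOR, by 1.67 ± 0.23 and SMAD6, an inhibitor of BMP signalling, by 1.28 ± 0.19. Of the genes named here, CRY1 and PDGFA were also called lower with 3MB in hypoxic WT cells. No gene was called by the genotype by compound contrast in hypoxia in the main test.

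With 3MB against vehicle in hypoxic CDK8as cells 13 of 24 glycolysis genes fell and 0 rose, with 18 falling adjusted over the list alone (median -0.51, adjusted p = 1.7e-11, and adjusted p = 0.015 with an estimated correlation). The number that fell was 15 with the GC offset, 17 in DESeq2 and 3 with the expression offset, where the median was -0.28 (adjusted p = 7.0e-04). It was 3 to 9 with any 1 of the 4 libraries left out. Of 44 other HIF targets 20 fell and 1, ZNF395 at 0.52 ± 0.14, rose, with 26 falling adjusted over the list alone (median -0.52, adjusted p = 1.6e-10, and adjusted p = 0.11 with an estimated correlation). With 1 library left out 4 to 17 fell, and ZNF395 was called in 1 of the 4 omissions. The 200 genes that rose most firmly with hypoxia in WT cells, which share no library with this comparison, had 80 lower and 2 higher (median -0.46, p = 8.8e-28, and p = 0.0023 with an estimated correlation). Cholesterol synthesis genes fell in 9 of 25 cases (median -0.36), ER unfolded protein response genes in 8 of 19, 17 adjusted over the list alone (median -0.51), and immediate early genes in 7 of 38 with 1 higher (median -0.42). ATF4 targets fell in 5 of 25 with 1 higher (median -0.41), MYC targets in 4 of 31 (median -0.32), G2/M genes in 3 of 30 (median -0.32), and heat shock genes in 2 of 15, 9 adjusted over the list alone (median -0.41). With 1 library left out, 0 to 8 cholesterol, 0 to 8 ER, 1 to 5 immediate early, 0 to 7 ATF4 (median -0.59 to -0.24), 0 to 1 MYC, 2 G2/M and 0 to 2 heat shock genes fell. HSPA5, an ER chaperone, fell by 1.45 ± 0.26, and CDC20, a mitotic regulator, by 1.06 ± 0.16. The HSPA5 call was lost without CDK8as DMSO hypoxia replicate 1 or CDK8as 3MB hypoxia replicate 2. Oxidative phosphorylation genes (2 of 50 lower, median -0.33), ribosomal protein genes (0 called of 50, median -0.36) and TCA cycle genes (0 called of 18, median -0.24) were also called as lists. Interferon response genes were called upward (4 of 34 higher and 2 lower, median 0.52, adjusted p = 0.0068). No call of these 11 lists held with an estimated correlation (adjusted p = 0.34 to 0.72). The ribosomal protein, TCA cycle and ATF4 calls were lost with the expression offset (0.853, 0.660 and 0.0640). The TCA cycle call was lost without CDK8as DMSO hypoxia replicate 2 (0.0961), and the ATF4 call without replicate 1 (0.253). The interferon call was lost without CDK8as DMSO hypoxia replicate 1 (0.0823) or CDK8as 3MB hypoxia replicate 2 (0.169). E2F targets (2 of 40 lower, called without CDK8as 3MB hypoxia replicate 2 at 0.0465), TGF-beta/SMAD targets (3 higher and 3 lower of 16) and p53 targets (3 higher and 5 lower of 30, with TP53I3 up by 1.04 ± 0.18 and PLK3 down by log2 -0.84 ± 0.16) were not called. The p53 list was called with the expression offset. The PLK3 call was lost without CDK8as DMSO hypoxia replicate 1 or CDK8as 3MB hypoxia replicate 1.

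**Figure D3:**
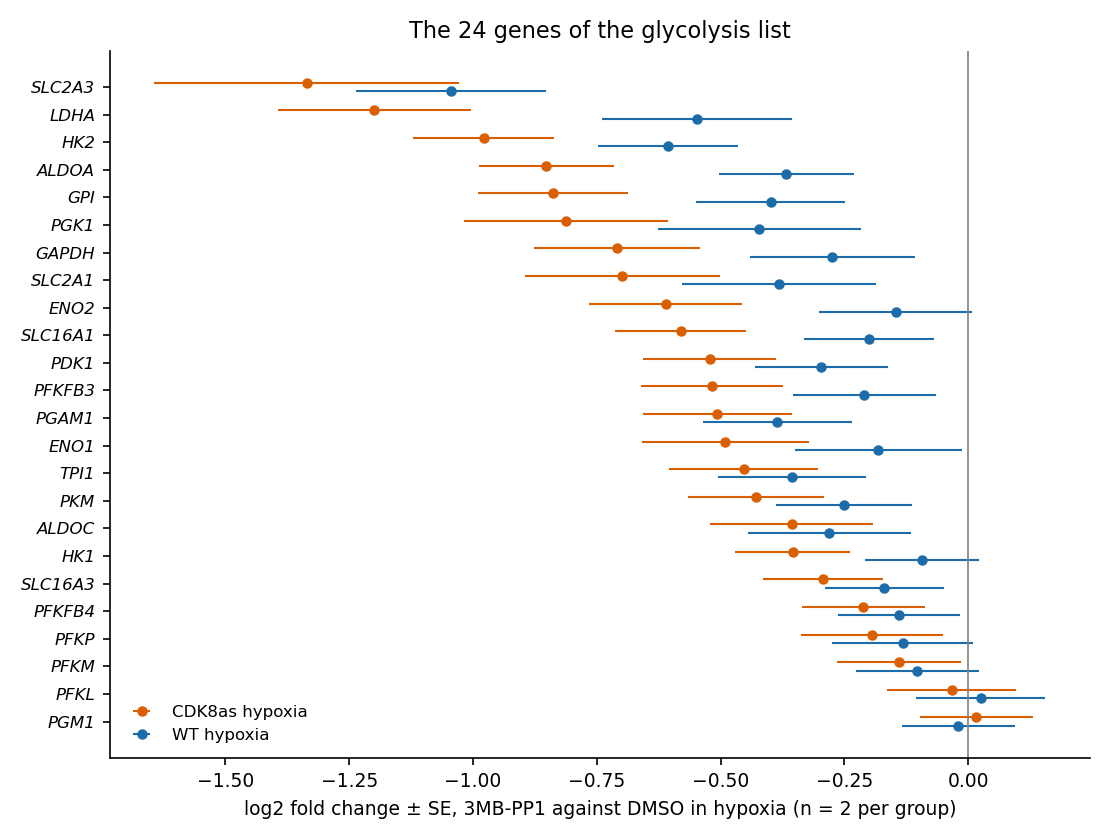
Log2 change with 3MB against vehicle in hypoxia for the 24 glycolysis genes in CDK8as and in WT cells, with points for the estimate and bars for the standard error. In CDK8as cells 13 genes were called lower (3 with the expression offset), and in WT cells 0 were called. The median in WT cells was -0.26, and no gene was called for the difference between genotypes.

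In this comparison 1498 genes were called, 816 higher and 682 lower, and 426 and 87 of them changed at least 2-fold. The count was 261 without CDK8as DMSO hypoxia replicate 1, and 367 and 326 without CDK8as 3MB hypoxia replicates 1 and 2. Log2 changes followed expression level across genes (Spearman -0.389), and the expression offset left 845 calls. The GC offset gave 1238 higher and 1425 lower. The CDK8as DMSO hypoxia libraries had the lowest TMM factors, 0.769 and 0.789. In each omission of a library the calls of HK2, LDHA, NDRG1, ANKRD37, CRY1 and PDGFA were kept.

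In normoxic CDK8as cells 3MB was compared with vehicle to ask which genes change with the compound without hypoxia. This too does not by itself separate kinase inhibition from other actions of 3MB. DBP (19:49133287-49140636), a transcription factor of the clock's output, rose by log2 1.51 ± 0.16 (SE, n = 2 per group, adjusted p = 9.7e-04). TNFRSF6B (20:62328005-62330037), a decoy receptor, rose by 1.94 ± 0.24 (adjusted p = 0.0038) and CD22, a surface lectin, by 1.73 ± 0.23 (adjusted p = 0.0038). CHAC1, which degrades glutathione and is an ATF4 target, fell by 3.17 ± 0.40 (adjusted p = 0.0038), and STC2, a secreted glycoprotein, by 1.15 ± 0.17 (adjusted p = 0.010). The exons of DBP and TNFRSF6B overlap those of SPHK2 and RTEL1-TNFRSF6B. ATF4 targets fell in 2 of 25 cases, 16 adjusted over the list alone (median -0.51, adjusted p = 2.3e-15, and adjusted p = 0.16 with an estimated correlation). None of 24 glycolysis genes was called, and 6 were lower adjusted over the list alone (median -0.29, adjusted p = 9.9e-07, and adjusted p = 0.083 with an estimated correlation). E2F targets (19 of 40 lower adjusted over the list alone, median -0.42), MYC targets (10 of 31, median -0.36) and heat shock genes (10 of 15, median -0.53) were called as lists with 0 single genes called. Interferon response genes were called upward (median 0.53, adjusted p = 1.6e-05). Those calls were lost with an estimated correlation (adjusted p = 0.16, 0.083, 0.16 and 0.36). Other HIF targets had 1 higher and 1 lower of 44 (median -0.13, adjusted p = 0.034, and adjusted p = 0.43 with an estimated correlation). That call was lost without CDK8as DMSO normoxia replicate 1 (0.761), 3MB normoxia replicate 1 (0.0575) and 3MB normoxia replicate 2 (0.0788). Called genes numbered 19, 17 higher and 2 lower, out of 1926 with an unadjusted p under 0.05. There were 258 in DESeq2 and 206 with the GC offset, of which 123 were higher and 83 lower. The count was 2 without either CDK8as DMSO normoxia library, and 6 and 1 without CDK8as 3MB normoxia replicates 1 and 2. The call of DBP was kept in each, while those of TNFRSF6B and CD22 were lost in 3 of these omissions, CHAC1 in 2 and STC2 in 4. Of the 19 genes, 9 rose in hypoxia with the compound too, against 0.891 from the shares called.

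In WT cells, whose kinase lacks the engineered pocket, 3MB was compared with vehicle as the background of the compound. In hypoxia CRY1 fell from 29.0 ± 4.4 to 10.6 ± 1.5 CPM (SD, n = 2), a log2 change of -1.45 ± 0.17 (SE, adjusted p = 0.0048). TSC22D3, a glucocorticoid-induced leucine zipper, fell by 1.40 ± 0.18 (adjusted p = 0.0077), and PDGFA by 1.1 ± 0.17 (adjusted p = 0.034). The clock genes TEF and CRY2 fell by 1.07 ± 0.16 (adjusted p = 0.021) and 0.94 ± 0.15 (adjusted p = 0.041). These 5 were all the genes called in WT hypoxia, out of 1391 with an unadjusted p under 0.05, and 4 of them also fell in CDK8as hypoxia, against 0.219 from the shares called. DESeq2 called 86 genes there, the GC offset 25 (5 higher and 20 lower), the expression offset 4 (1 higher and 3 lower) and a fit on the 4 libraries alone 0. The count was 1 and 2 without WT DMSO hypoxia replicates 1 and 2, and 1 and 21 without WT 3MB hypoxia replicates 1 and 2. TEF and CRY2 lost their calls in all 4 omissions, TSC22D3 and PDGFA in 2 and CRY1 in 1, without WT DMSO hypoxia replicate 1. The expression offset also took those of CRY2 and PDGFA (0.0523). Glycolysis genes had no member called in WT hypoxia and 2 lower adjusted over the list alone (median -0.26, adjusted p = 5.8e-08, and adjusted p = 0.054 with an estimated correlation). Other HIF targets had none and 15 (median -0.32, adjusted p = 3.0e-11, and adjusted p = 0.078 with an estimated correlation). The 200 genes that rose most firmly with hypoxia in CDK8as cells had 2 lower (median -0.24, p = 6.4e-19, and p = 0.0039 with an estimated correlation). Cholesterol synthesis (11 of 25 lower adjusted over the list alone, median -0.29), ER unfolded protein response (6 of 19, median -0.41) and ATF4 targets (5 of 25, median -0.30) were called lower. Metallothioneins were called higher (4 of 9 higher and 1 lower adjusted over the list alone, median 0.44, adjusted p = 0.0086). All 4 calls were lost with an estimated correlation (adjusted p = 0.22, 0.22, 0.33 and 0.31). The metallothionein call was lost without WT DMSO hypoxia replicate 2 (0.154) or WT 3MB hypoxia replicate 1 (0.0912). Replication-dependent histones were called lower (median -0.87, adjusted p = 1.8e-05) and interferon response genes higher (median 0.18, adjusted p = 0.045). Neither call held with an estimated correlation (adjusted p = 0.22 and 0.72). Other lists called lower in CDK8as hypoxia were also called lower here: immediate early (median -0.23), G2/M (-0.17), MYC (-0.18), heat shock (-0.33), oxidative phosphorylation (-0.25), ribosomal protein (-0.26) and TCA cycle genes (-0.14). None of the 7 held with an estimated correlation (adjusted p = 0.29 to 0.72). The MYC, ribosomal protein and TCA cycle calls were lost with the expression offset and without WT 3MB hypoxia replicate 2 (0.0602, 0.489 and 0.144). The last 2 were also lost without WT DMSO hypoxia replicate 1 (0.474 and 0.234).

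In WT normoxia edgeR called 0 genes, out of 1303 with an unadjusted p under 0.05, DESeq2 called 51, and the GC offset 4. CDK8 changed by log2 -0.33 ± 0.16 there (SE, n = 2 per group, adjusted p = 0.60). ATF4 targets had 10 of 25 lower adjusted over the list alone (median -0.33, adjusted p = 2.2e-11) and heat shock genes 9 of 15 (median -0.45, adjusted p = 9.6e-09). Glycolysis genes had 0 of 24 (median -0.22, adjusted p = 0.0010), and each of these calls was lost with an estimated correlation (adjusted p = 0.21). E2F targets (median -0.23, adjusted p = 8.0e-07), MYC targets (-0.29, adjusted p = 9.6e-09), cholesterol synthesis (-0.29, adjusted p = 9.6e-09) and oxidative phosphorylation genes (-0.29, adjusted p = 8.2e-07) were also called lower. None held with an estimated correlation (adjusted p = 0.56, 0.21, 0.21 and 0.62). RNAs without a poly(A) tail were called lower as well (median -0.89, adjusted p = 0.033, and adjusted p = 0.25 with an estimated correlation). G2/M (-0.16), ribosomal protein (-0.24) and ER unfolded protein response genes (-0.21) were called lower and mesenchymal genes higher (0.33). These calls too were lost with an estimated correlation (adjusted p = 0.62, 0.78, 0.62 and 0.38). Oxidative phosphorylation was called higher without WT DMSO normoxia replicate 1 (median 0.12, adjusted p = 0.0027). The count of called genes was 3039 without WT DMSO normoxia replicate 2, which leaves replicate 1 of that group alone, and 1 without WT 3MB normoxia replicate 2.

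**Figure D4:**
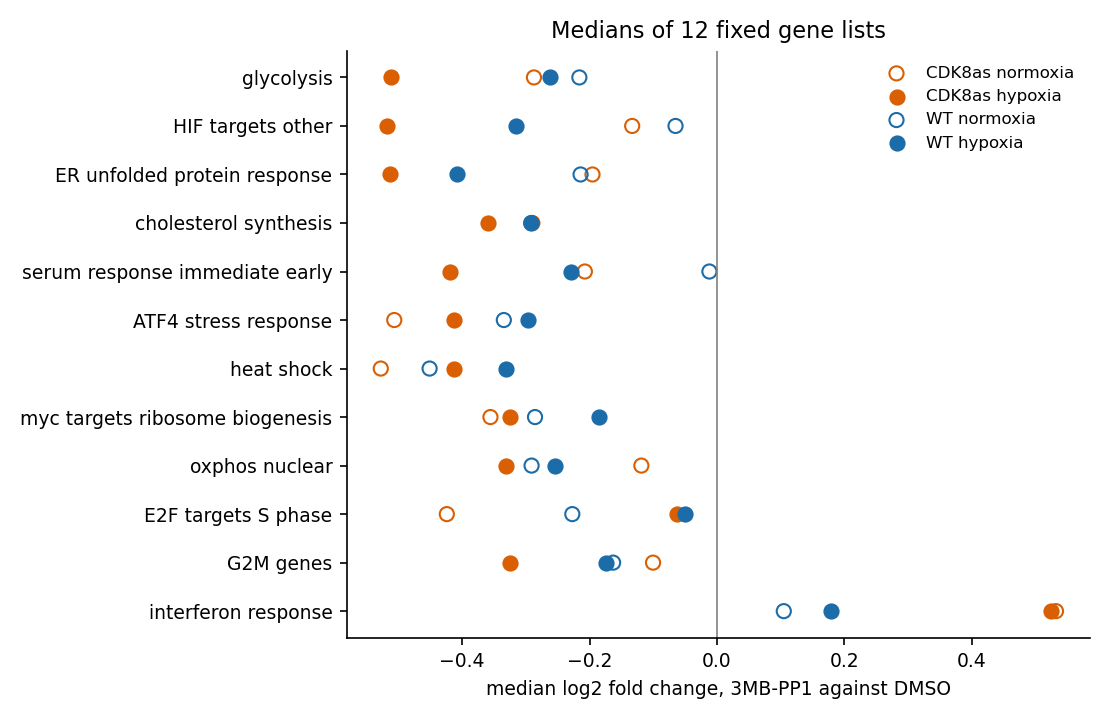
Median log2 change of 12 gene lists with 3MB against vehicle in CDK8as normoxia, CDK8as hypoxia, WT normoxia and WT hypoxia. The glycolysis medians were -0.29, -0.51, -0.22 and -0.26, and those of other HIF targets -0.13, -0.52, -0.07 and -0.32.

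Whether the compound acted differently on CDK8as and WT cells was tested as an interaction. In hypoxia the glycolysis list fell further in CDK8as cells (median difference -0.28, adjusted p = 6.3e-05), which was lost with an estimated correlation (adjusted p = 0.16) and with the expression offset (0.165), and no member was called. Other HIF targets differed by -0.13 (adjusted p = 0.032, and adjusted p = 0.84 with an estimated correlation) and metallothioneins by -0.42 (adjusted p = 0.0035, and adjusted p = 0.70 with an estimated correlation). The HIF target call was lost without WT DMSO hypoxia replicate 1 (0.0991), WT 3MB hypoxia replicate 2 (0.0760), CDK8as DMSO hypoxia replicate 1 (0.332) and CDK8as 3MB hypoxia replicate 2 (0.155), and the metallothionein call without the last of these (0.0631). Immediate early (median -0.20), MYC (-0.13), G2/M (-0.15) and ER unfolded protein response genes (-0.12) were also called lower in hypoxia (adjusted p = 0.032 to 0.047). None of these held with an estimated correlation (adjusted p = 0.84). Log2 differences followed expression level across genes (Spearman -0.253). No gene was called by edgeR in hypoxia, out of 988 with an unadjusted p under 0.05, and DESeq2 called 26 and edgeR without a filter on low counts 35. In normoxia edgeR and DESeq2 each called 0 genes, out of 336 with an unadjusted p under 0.05 in edgeR, and edgeR called 804 without WT DMSO normoxia replicate 2. The glycolysis (median -0.10, adjusted p = 0.11) and other HIF target lists (median -0.02, 0.01 with the expression offset, adjusted p = 0.54) were not called in normoxia. The first was called without WT DMSO normoxia replicate 1 (0.0232) or a filter on low counts (0.0262), the second without CDK8as DMSO normoxia replicate 2 (0.0146). Log2 changes with the compound had a Spearman correlation across genes of 0.518 between the genotypes in hypoxia and 0.396 in normoxia.

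Whether the compound acted differently in hypoxia and normoxia was tested in CDK8as cells. DBP differed by log2 -2.21 ± 0.22 (SE, n = 2 per group, adjusted p = 4.6e-04), since it rose with the compound in normoxia and fell in hypoxia, and PDGFA differed by -1.65 ± 0.25 (adjusted p = 0.020). With 3MB in WT cells DBP changed by 0.60 ± 0.15 in normoxia and -0.84 ± 0.15 in hypoxia, neither called. The difference between these was not tested. In CDK8as cells PKD2 differed by 1.89 ± 0.25 (adjusted p = 0.0095) and BDNF, a neurotrophin, by 1.27 ± 0.19 (adjusted p = 0.020). Other HIF targets differed by a median of -0.31, with 0 of 44 called and 10 lower adjusted over the list alone (adjusted p = 6.5e-06, and adjusted p = 0.35 with an estimated correlation), and glycolysis genes by -0.22 (adjusted p = 0.0017, and adjusted p = 0.35 with an estimated correlation, lost with the expression offset at 0.654). The 200 genes raised by hypoxia in WT cells differed by a median of -0.46 and the 200 lowered ones by 0.41 (p = 8.9e-04 and 0.016 with an estimated correlation). This interaction called 17 genes, 6 higher and 11 lower, against 228 in DESeq2, 126 with the GC offset (64 higher and 62 lower) and 23 with RLE (12 higher and 11 lower). The count was 2 without either CDK8as DMSO normoxia library, and 1 and 44 without CDK8as DMSO hypoxia replicates 1 and 2. It was 3 and 1 without CDK8as 3MB normoxia replicates 1 and 2, and 1 without either CDK8as 3MB hypoxia library. DBP was kept in each, while of the 8 omissions PDGFA lost its call in 6, PKD2 in 5 and BDNF in 7.

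Genotypes were compared directly to ask how CDK8as cells differ from WT cells apart from the compound. The labels do not give the number of clones behind either. With vehicle in normoxia LY6D, a surface protein of epithelia, was higher in CDK8as cells by log2 6.58 ± 0.49 (SE, n = 2 per group, adjusted p = 1.3e-06), KRT7, a keratin, by 4.66 ± 0.22 and GRHL3, an epithelial transcription factor, by 4.01 ± 0.20. ZNF227 (19:44711700-44741421), a zinc finger gene whose exons overlap ZNF235, was lower by log2 -6.38 ± 0.32 (adjusted p = 6.9e-09), at 0.174 against 14.8 CPM. SLC38A5, an amino acid transporter, SLC2A3, a glucose transporter, and MAOB, an amine oxidase, differed by -6.26 ± 0.35, -3.41 ± 0.35 and -3.16 ± 0.24. Metallothioneins were lower in 6 of 9 cases, 8 lower and 1 higher adjusted over the list alone (median -2.22, adjusted p = 2.3e-12, and adjusted p = 0.052 with an estimated correlation). Intestinal epithelium genes were higher in 5 of 12 cases with 1 lower (median 0.61, adjusted p = 7.5e-04, and adjusted p = 0.65 with an estimated correlation). G2/M genes were lower in 5 of 30 cases (median -0.42, adjusted p = 3.0e-07, and adjusted p = 0.84 with an estimated correlation), and in 1 to 22 over omitted libraries (median -0.63 to -0.23). Mesenchymal genes split at 3 and 3 of 10 (median 0.14 but mean -0.30, adjusted p = 0.86). TGF-beta/SMAD targets (4 higher and 1 lower of 16, median 0.27) and p53 targets (3 higher and 2 lower of 30, median 0.28) each had an adjusted p of 0.040, lost with an estimated correlation (adjusted p = 0.35 and 0.84). The TGF-beta/SMAD call was also lost without WT DMSO normoxia replicate 1 (0.165) or 2 (0.168) or CDK8as DMSO normoxia replicate 1 (0.0738), and the p53 call without WT DMSO normoxia replicate 2 (0.540) or CDK8as DMSO normoxia replicate 1 (0.140). Glycolysis (3 higher and 2 lower) and other HIF target genes (5 higher and 3 lower) were not called as lists. In all 1073 genes were called, 515 higher and 558 lower. The count was 4294 without WT DMSO normoxia replicate 2, 536 and 508 without CDK8as DMSO normoxia replicates 1 and 2, and 322 in a fit on these 4 libraries alone.

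With vehicle in hypoxia NRP2, a semaphorin receptor, was higher in CDK8as cells by log2 5.43 ± 0.53 (SE, n = 2 per group, adjusted p = 1.0e-05), FAM83A by 4.86 ± 0.35 and GRHL3 by 4.31 ± 0.20. SLC2A3 was lower by log2 -5.25 ± 0.25, at 1.59 ± 0.34 against 60.3 ± 11 CPM (SD). Cholesterol synthesis genes were higher in 17 of 25 cases and lower in 2, among them TM7SF2, a sterol reductase, at -1.60 ± 0.20 (median 0.63, adjusted p = 1.0e-05, and adjusted p = 0.80 with an estimated correlation). The p53 targets were higher in 14 of 30 cases with 3 lower (median 0.49, adjusted p = 3.7e-04, and adjusted p = 0.62 with an estimated correlation). Intestinal epithelium genes were higher in 7 of 12 with 1 lower (median 1.00, adjusted p = 0.0032, and adjusted p = 0.80 with an estimated correlation). Glycolysis genes (3 higher and 3 lower of 24, median 0.05 but mean -0.19, and median -0.19 with the expression offset, which called it at adjusted p = 0.0070), other HIF targets (10 higher and 8 lower of 44), metallothioneins (1 higher and 3 lower of 9) and TGF-beta/SMAD targets (4 higher and 4 lower of 16) were not called as lists. In all 3200 genes were called, 1531 higher and 1669 lower. The count was 1880, 1711 and 1844 without WT DMSO hypoxia replicates 1 and 2 and CDK8as DMSO hypoxia replicate 1. Genes higher in CDK8as cells in both oxygen levels numbered 345 against 50.7 from the shares called, lower ones 397 against 59.8, and opposite ones 5 against 110.

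With 3MB, LY6D was higher in CDK8as cells by log2 6.06 ± 0.47 in normoxia and 6.42 ± 0.46 in hypoxia (SE, n = 2 per group), and ZNF227 differed by -5.44 ± 0.30 and -6.79 ± 0.35. MT2A differed by -3.63 ± 0.22 in normoxia. Metallothioneins were lower in 5 of 9 cases with 1 higher in normoxia (median -2.0, adjusted p = 0.031 with an estimated correlation) and in hypoxia (median -1.08, adjusted p = 0.17 with an estimated correlation). TGF-beta/SMAD targets were higher in 5 of 16 cases with 2 lower in normoxia (median 0.35, adjusted p = 1.9e-04, and adjusted p = 0.031 with an estimated correlation). The p53 targets were higher in 8 and 13 of 30 cases with 1 and 2 lower (medians 0.46 and 0.51, adjusted p = 0.10 and 0.14 with an estimated correlation). Intestinal epithelium genes were higher in 7 and 5 of 12 with 1 and 2 lower (medians 0.94 and 0.71, adjusted p = 0.37 and 0.81 with an estimated correlation). In hypoxia glycolysis genes were lower in 5 of 24 cases with 1, PFKFB3 at 0.62 ± 0.14, higher (median -0.28, adjusted p = 1.6e-04, and adjusted p = 0.14 with an estimated correlation). The PFKFB3 call was lost without WT 3MB hypoxia replicate 1 (0.0563) or 2 (0.0927) or CDK8as 3MB hypoxia replicate 1 (0.0836). SLC2A3, PFKFB4 and HK1 differed by -5.55 ± 0.26, -0.87 ± 0.12 and -0.76 ± 0.12. Cholesterol synthesis genes were higher in 14 of 25 cases with 1 lower (median 0.59, adjusted p = 0.44 with an estimated correlation). The other HIF targets in hypoxia and the glycolysis list in normoxia were not called (adjusted p = 0.19 and 0.070). The latter was called without WT 3MB normoxia replicate 1 (0.0272), without a filter on low counts (0.0159) and in a fit on only the groups compared (0.0463). Called genes numbered 945 in normoxia, 484 higher and 461 lower, and 1805 in hypoxia, 936 higher and 869 lower. Without WT 3MB replicates 1 and 2 and CDK8as 3MB replicates 1 and 2 the counts were 453, 545, 493 and 480 in normoxia and 846, 1090, 952 and 893 in hypoxia.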

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

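The genotype by oxygen comparison, both offsets and the tests of explanations were chosen only after results were seen; the other comparisons and lists here were planned.

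Glycolysis genes responded differently to 3MB in hypoxic CDK8as and WT cells by a test of the difference itself, with a median log2 difference of -0.28 (adjusted p = 6.3e-05). The list fell in WT cells too (median -0.26, camera adjusted p = 5.8e-08, and adjusted p = 0.054 with an estimated correlation). No member was called for the difference between genotypes, over all genes or adjusted over the list alone. The difference was not called with an estimated correlation (0.163) or with the expression offset (0.165), and its adjusted p ran from 1.6e-06 (no filter on low counts) to the last of these over all alternatives and omissions of a library. HK2 and LDHA were among the 13 of 24 genes called lower in CDK8as cells (3 to 9 with any 1 of the 4 libraries left out and 3 with the expression offset), and 0 were called in WT cells.

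The response of CDK8as cells to 3MB differed between oxygen levels in 17 genes, by a test of the difference, among them DBP at log2 -2.21 ± 0.22 and PKD2 at 1.89 ± 0.25, whose call was lost in 5 of the 8 omissions below. The count was 2 without either CDK8as DMSO normoxia library, 1 and 44 without CDK8as DMSO hypoxia replicates 1 and 2, 3 and 1 without CDK8as 3MB normoxia replicates 1 and 2, and 1 without either CDK8as 3MB hypoxia library. The 200 genes most firmly raised by hypoxia in WT cells differed by a median of -0.46 and the 200 most firmly lowered by 0.41, both called with an estimated correlation (p = 8.9e-04 and 0.016). The GC and expression offsets were not applied to these lists, and log2 differences in this interaction followed expression level across genes (Spearman -0.217). The raised genes had medians of 0.06 with 3MB in normoxia and -0.46 in hypoxia, and the lowered genes -0.33 and 0.05, and those of 0.06 and 0.05 were not called with an estimated correlation (p = 0.49 and 0.50). In WT cells the lists derived in CDK8as cells moved the same ways. There the raised genes had medians of 0.07 in normoxia and -0.24 in hypoxia, and the lowered genes -0.16 and 0.11. DBP also rose with 3MB in WT normoxia (0.60 ± 0.15, adjusted p = 0.34) and fell in WT hypoxia (-0.84 ± 0.15, adjusted p = 0.066), neither called. The difference between oxygen levels was not tested in WT cells.

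The response to hypoxia with vehicle differed between the genotypes in 199 genes, by a test of the difference, and in 12 in a fit on only the groups compared. The count was 2982 without WT DMSO normoxia replicate 2, 84 and 46 without WT DMSO hypoxia replicates 1 and 2, 57 and 47 without CDK8as DMSO normoxia replicates 1 and 2, and 39 without CDK8as DMSO hypoxia replicate 1. Cholesterol synthesis genes differed by a median of 0.80 and metallothioneins by 0.92. Neither list was called with an estimated correlation (0.14).

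Of the patterns above, the fall of glycolysis genes with 3MB in CDK8as hypoxia was weighed. A trend of the fold change with expression level was argued against as the whole cause: with the trend removed, the mean of the list still differed by -0.292 between compound and vehicle (-0.542 before), against a largest difference between replicates of 0.11, although only 3 genes were then called. An action of 3MB that does not need the analog-sensitive kinase stays open. WT cells in hypoxia moved the same way (mean -0.290, and -0.152 with the trend removed), and the difference between genotypes was not called with an estimated correlation (0.163). In normoxia the mean with the trend removed was -0.227 in CDK8as cells and -0.131 in WT cells, so a fall was seen there too. CDK8as vehicle libraries in hypoxia that stand apart, after which the genotypes would match with 3MB, cannot be told apart from a kinase effect: CDK8as cells with 3MB in hypoxia differed from WT cells by a median of -0.277 in this list, called (adjusted p = 1.6e-04) but not with an estimated correlation (0.14). With vehicle in hypoxia the list was not called between the genotypes (median 0.05, mean -0.19). Inhibition of the analog-sensitive kinase, the biological explanation the design gives, may account for the part by which CDK8as cells exceeded WT cells.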

How the results depend on the processing

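The GC and expression offsets and the genotype by oxygen comparison were chosen only after results were seen; the other settings were planned. Of the called genes and lists, 1 list reversed its direction. Oxidative phosphorylation genes with 3MB in WT normoxia were called higher without WT DMSO normoxia replicate 1 (adjusted p = 0.0027) and lower without replicate 2 (3.1e-15). RLE moved no count of called genes by more than 1.5 times. The cause was not tested for the changes below, except that a fit on fewer libraries has fewer residual degrees of freedom and an omitted library leaves its replicate alone.

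Without a filter on low counts, called genes numbered 271 for 3MB in CDK8as normoxia, 108 and 124 in WT normoxia and hypoxia, and 1717 between genotypes with vehicle in normoxia. It gave 7 and 35 for genotype by compound in normoxia and hypoxia, 213 for compound by oxygen and 669 for genotype by oxygen. DESeq2 gave 258 for 3MB in CDK8as normoxia, 51 and 86 in WT normoxia and hypoxia, 26 for genotype by compound in hypoxia, 228 for compound by oxygen and 574 for genotype by oxygen. The GC offset gave 206 and 2663 for 3MB in CDK8as normoxia and hypoxia, 4 and 25 in WT normoxia and hypoxia, 126 for compound by oxygen and 476 for genotype by oxygen. In CDK8as hypoxia most called genes were higher (816 against 682 lower), but most were lower with a block (1391 and 1514), the GC offset (1238 and 1425) or a fit on only the groups compared (758 and 879). The side with more called genes also changed in at least 1 setting or omission for hypoxia and for genotype in each background, compound by oxygen and genotype by oxygen. The expression offset changed the sign of medians of lists not called, among them ribosomal proteins with hypoxia in WT cells (0.27 to -0.11) and glycolysis by genotype and oxygen (0.09 to -0.19). Between genotypes with vehicle in hypoxia it took the glycolysis median from 0.05 to -0.19 and called it (adjusted p = 0.0070). It gave 845 for 3MB in CDK8as hypoxia and 129 for genotype by oxygen. A fit on only the groups compared gave 2428 for hypoxia in WT cells with vehicle, 395 for 3MB in CDK8as normoxia, and 0 in WT hypoxia, against 5 in edgeR over all libraries, 1391 at an unadjusted p under 0.05 and 86 in DESeq2. It gave 322, 1727 and 3052 between genotypes with vehicle in normoxia and with 3MB in normoxia and hypoxia, 87 for compound by oxygen and 12 for genotype by oxygen.

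With a replicate block, called genes numbered 290 and 2905 for 3MB in CDK8as normoxia and hypoxia, and 35 and 51 in WT normoxia and hypoxia. The block gave 1875 and 1434 between genotypes in normoxia with vehicle and with 3MB, 5 for genotype by compound in hypoxia, 205 for compound by oxygen and 741 for genotype by oxygen. The labels do not say that equal replicate numbers share a day or batch. Library numbers run in 1 series for each replicate number, and 23 of 28 correlations between the replicate differences of group pairs exceeded 0.1 (0.0463 to 0.299, median 0.138).

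Leaving out each library in turn gave 3997 to 7203 called genes for hypoxia in WT cells with vehicle, 2603 to 3017 in WT cells and 2996 to 3294 in CDK8as cells with 3MB. It gave 1 to 6 and 261 to 1058 for 3MB in CDK8as normoxia and hypoxia, and 0 to 3039 and 1 to 21 in WT normoxia and hypoxia. It gave 508 to 4294 and 1711 to 2320 between genotypes with vehicle in normoxia and hypoxia, 453 to 545 and 846 to 1090 with 3MB, 0 to 804 for genotype by compound in normoxia, 1 to 44 for compound by oxygen and 39 to 2982 for genotype by oxygen. The count of 3039 came without WT DMSO normoxia replicate 2, as did 4294, 804 and 2982, and the lowest for hypoxia in WT cells without WT DMSO hypoxia replicate 2.

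With an estimated correlation the adjusted p was 0.106 for other HIF targets with 3MB in CDK8as hypoxia, 0.0535 for glycolysis in WT hypoxia and 0.163 for glycolysis by genotype and compound in hypoxia. With the preset correlation, omitted libraries gave 4.7e-11 to 1.5e-07, 6.9e-07 to 2.4e-05 and 3.4e-05 to 0.0145 for these, and the expression offset 0.165 for the last. Of 141 fixed list results, 86 lost their call with an estimated correlation, 32 with fry, 17 with the expression offset, 5 with the GC offset, 5 in a fit on only the groups compared, 3 without a filter and 0 with RLE or a block. The 141 include lists not called in the main test. Calls were gained in 7 results with fry, 5 without a filter and 3 with the expression offset. A block and a fit on only the groups compared gained 1 each. Of 292 results for named genes, HK2, LDHA and CRY1 in CDK8as hypoxia kept their calls in each setting and omission, while 20 lost theirs with the expression offset, 25 in a fit on only the groups compared, 2 with the GC offset, 1 with RLE, 1 without a filter and 0 in DESeq2 or with a block; counting each result once for each omitted library, a call was lost 274 times and unchanged 1018 times. Depth limits genes under the floor of 3 counts (0.0773 to 0.249 CPM), so SLC2A3 in CDK8as normoxia with 3MB, at 0.0877 CPM, lies under the floors of its libraries, of which the lower is 0.142 CPM.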

Other observations

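The clock and single-exon gene lists, both offsets, the genotype by oxygen comparison and the tests of explanations were chosen only after results were seen. The ribosomal protein list and the other comparisons were planned.

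Of 10 genes of the circadian clock's repressor and output arms, 3 were called lower with 3MB in WT hypoxia and 5 in CDK8as hypoxia. In WT hypoxia 10 of 10 had a negative log2 change (median -1.01) and CRY1, CRY2 and TEF were called, and in CDK8as hypoxia 9 of 10 did (median -0.77) and CRY1, CRY2, PER2, DBP and TEF were called, with CRY2 at -1.24 ± 0.15, PER2 at -1.31 ± 0.26, DBP at -0.70 ± 0.15 and TEF at -0.58 ± 0.15. PER3 was at 0.15 there, and NR1D1 at -0.17 in WT and -0.26 in CDK8as cells, none of them called. Of the 4 omissions of a library, the calls of TEF and CRY2 in WT cells were lost in 4, and in CDK8as cells those of TEF in 4, DBP in 3 and PER2 in 1. The expression offset took those of CRY2 in WT and TEF in CDK8as cells. In normoxia DBP and NR1D1 rose with 3MB in CDK8as cells (list median 0.20), and the median in WT cells was -0.00. DBP and NR1D1 moved the same way in WT cells, by 0.60 ± 0.15 and 1.14 ± 0.25, neither called. None of the 10 genes was called for the difference between genotypes in normoxia. The call of NR1D1 was lost with RLE (adjusted p = 0.0505) and without any 1 of the 4 libraries (0.145 to 0.437). The difference between genotypes in hypoxia had a median of 0.08 and no gene called by edgeR.

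Inhibition of the analog-sensitive kinase was argued against as the whole cause of the lower clock genes, since WT cells, which lack it, had a mean difference of -0.943 (CDK8as -0.743), beyond the largest difference between replicates of any group, 0.461. The 7 genes not called in WT hypoxia, which leave out CRY1, CRY2 and TEF that prompted the list, had a mean of -0.855 there, against 0.526. A trend with GC content or expression level was argued against, as the higher of the medians under the 2 offsets in WT hypoxia was -0.986. A shift of clock phase between the cultures cannot be told apart from a direct effect, because the opposite-arm genes ARNTL, CLOCK, NPAS2 and NFIL3 went both ways around a mean of 0.00696 in WT and -0.0724 in CDK8as hypoxia, where ARNTL was called higher (0.56) and NFIL3 lower (-0.95), and samples were taken at 1 time. An action of 3MB outside the engineered kinase may be at work, as a hypothesis found and tested on the same data.

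Genes with a single exon were lower in hypoxia than genes with several in each of the 4 comparisons (medians -0.22, -0.45, -0.19 and -0.29 for 293 genes, against -0.02, -0.02, -0.04 and -0.02 for 13355). Bias with GC content, transcript length or expression level was argued against as the whole cause, as the smallest of the 4 falls after regression on them was -0.169, against a largest difference between replicates of 0.106. Genomic DNA in the normoxia libraries was argued against as the whole cause: in the 63 single-exon genes of 5 to 20 CPM the smallest fall was -0.269, against a replicate difference of 0.230, and their median loss of 2.52 to 6.41 CPM exceeded the 0.321 to 0.570 CPM per gene seen in olfactory receptor genes. The CPM per gene were not scaled by gene length, which limits that comparison. In the 82 single-exon genes of at least 20 CPM the differences were -0.05, -0.21, -0.01 and -0.04, against a replicate difference of 0.111. No biological explanation was tested.

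Cytosolic ribosomal protein genes rose with hypoxia in CDK8as cells (median 0.82), a list call lost with an estimated correlation (adjusted p = 0.72) and with the expression offset (median 0.15, adjusted p = 0.612, 0 genes called). The difference between genotypes in this response had a median of 0.56 (adjusted p = 2.9e-07, and adjusted p = 0.76 with an estimated correlation). In WT cells the list was not called (median 0.27, and -0.11 with that offset), but it was called higher without WT DMSO normoxia replicate 1 (median 0.779, adjusted p = 4.0e-09) or WT DMSO hypoxia replicate 2.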
